A study of Mus musculus with 64 samples.

How the data were processed

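RNA from the cortex and the hippocampus of aged mice was measured on 64 one-colour arrays. Per the labels' protocols, total RNA was labelled with Cy3 and hybridised to Agilent mouse arrays, and each of the 16 groups held 4 biological replicates. A group is one brain region, one of 4 genotypes and one of 2 treatments, vehicle or 12 mM nicotinamide riboside (NR), a precursor of NAD+, in the drinking water. The series' design text gives 6 months of NR, whereas the treatment protocol describes 3 months before behavioural testing and continuation through it. Ages ran from 22 to 24 months, and both sexes were used. Nothing in the labels ties an array from one region to an array from the other through a shared animal, so arrays were treated as separate samples and p-values measure the spread between them. Arrays with one replicate number agree in sex and age across regions for all 4 numbers in 2 of 8 combinations of genotype and treatment (WT NR and AD vehicle) and not in the 6 others. Some animals may therefore have given both regions, and n in fits over both regions may exceed the number of animals.

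The deposited values came in 2 kinds. Per the file headers, the scanner files were written by Agilent Feature Extraction 12.0.3.1 and give a spot intensity that the software had background-subtracted and detrended within each array, with no normalization between arrays; the same files give the raw median intensity of each spot and of its local background. The deposited series table holds a score per probe and array without a stated scale. Set against the scanner files, each of its 64 columns equalled the z-score over one array of the log2 processed intensity, with a largest difference of 0.00502. Its values are therefore centred and scaled per array, and it was used as an alternative only. The headers name the mouse build mm9 for the design, which differs from the build of the gene table used for names (GRCm38.p6), so no coordinates are printed.

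Each array held 62976 spots, of which 3671 were controls and were left out. The 59305 other spots represent 55681 probes. Spots of one probe were averaged after removal of outlier spots, and 28331 probes were matched to 1 gene symbol of the gene table through the accession given for the probe in the files; the other 27350 had no symbol here and were not analysed. These probes name 21368 genes, 5754 of them through more than 1 probe, for which the probe with the highest mean over all arrays was used. Values were log2 processed intensity minus the array's own 75th percentile. That percentile ranged from 348 to 7638 in scanner units, and for arrays precision is limited by their number. A gene was tested where its probe was well above background on all 4 arrays of at least 1 group, which left 15957 genes in cortex, 15965 in hippocampus and 16303 over both regions. Where no array of one group was well above background the difference is given as a bound ("at least N-fold"), the brighter group's mean against, per array, the higher of the dim probe's own signal and the lowest signal well above background.

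Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, eBayes, Benjamini-Hochberg adjustment over all genes tested). Within a region, all 32 arrays entered one fit with a mean per group and sex as a covariate. Over both regions, all 64 arrays entered a fit with region, AD transgenes, Polb copy, NR and sex, and the slide as a random block, whose consensus correlation was 0.0952. Each of the 8 slides held 8 arrays of one genotype in one region. Within a region, slide and genotype therefore cannot be told apart, whereas NR and vehicle arrays of one genotype shared a slide. On every slide the 4 vehicle arrays held the first line of positions and the 4 NR arrays the second, so an effect of NR and one of position cannot be told apart. All p-values given with a log2 difference are adjusted and come from limma, with ± as its SE; group means carry ± SD. A gene was called at an adjusted p under 0.05.

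A total of 44 gene lists (896 members, 880 on the array) were tested with camera at a preset correlation of 0.01, adjusted over the lists within a comparison. Each was run again with an estimated correlation and with fry, which tests whether a list moves one way without comparing it with other genes. Over all comparisons camera called 175 lists, of which 1 was kept with the estimated correlation. Fry, run on every list, called 50, not all of them among the 175. Members of a list are counted over all genes tested and adjusted over the list alone. A cell marker score is the mean over a list of log2 deviations from the region's mean.

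The lists, designs, alternatives and the rule for the genes named were fixed before the data were examined. Apart from Polb, App, Mapt and Thy1, named genes were those called with no overlap between the groups' arrays (the adjusted p alone for comparisons over several groups), up to 10 each way for the pooled genotype contrasts, for ADPolb vehicle against WT and for NR in ADPolb and over genotypes, and up to 5 each way elsewhere; where under 5 passed, the 5 with the smallest p. Up to 4 members with the smallest p were added from each list past the threshold and from 7 lists on DNA repair, DNA damage, NAD metabolism, sirtuins, microglia, inflammation and choroid plexus in every comparison. Sex-linked genes and unnamed transcripts were left out of that rule, and some genes that it names are not reported here.

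The alternatives were normexp background correction with an offset of 50, quantile normalization, the deposited series table, no filter on dim probes, no sex term, age as a covariate, the replicate number as a block, the mean of all probes of a gene, a fit of only the groups compared, and each array left out in turn. Normexp was run on median spot intensity, since mean intensity was not among the columns. For the pooled fits, no block, 1 mean per slide, vehicle arrays only and a fold change of at least 1.5 were added. After the data were seen, fits without doubted arrays, with sex taken from the arrays and of the cortex lists without the array of non-uniform spots were added. With normexp the median of all genes stood at -0.16, -0.12 and -0.15 in the AD, Polb and ADPolb cortex against WT and at 0.12 in the AD hippocampus, against -0.08, -0.03, -0.08 and 0.04 here, so that small differences are relative to that shift.

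On simulated arrays with 200 changed genes, the cortex AD against WT comparison recovered 40% of 2-fold and 80% of 4-fold changes with 2 false calls, and the hippocampus one recovered 57% and 89% with 5. The simulated noise was independent between genes and arrays and held no differences of slide or tissue. Its false calls therefore do not give the error rate in the real data. Python 3.11.15 with pandas 2.3.3 read the files, and figures were drawn with matplotlib 3.10.9.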

Results

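Gene expression was measured in the cortex and the hippocampus of 4 genotypes of aged mice: wild type (WT); 3xTgAD (AD), a triple-transgenic model of Alzheimer's disease; Polb heterozygotes (Polb), which carry 1 working copy of the gene for DNA polymerase β, an enzyme of base excision repair; and the cross of the latter pair (ADPolb). Each genotype had received vehicle or NR, which gave 16 groups of 4 arrays. The 75th percentile of intensity lay between 348 and 1189 on all arrays but the first AD NR array of cortex, where it was 7638. On that array 26764 spots (45.1%) were marked non-uniform, and 8465 of the genes tested in cortex had no value. Correlations between arrays of one group were lowest in that group (0.865) and otherwise ran from 0.941 to 0.993.

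Polb, the targeted gene, was lower in animals labelled heterozygous. Over both regions its level was 0.39 ± 0.37 (SD, n = 32) in Polb and ADPolb arrays and 1.11 ± 0.36 (n = 31) in the others, in log2 units relative to each array's 75th percentile, and the difference was -0.72 ± 0.11 (adjusted p = 0.000407). With 1 mean per slide the Polb level still differed by -0.72, at an adjusted p of 0.312, and in vehicle arrays alone by -0.49 (0.214), so it passed in neither. The 16 NR-treated heterozygote arrays lay close together. Their group means were 0.22 ± 0.10 and 0.41 ± 0.11 in cortex and 0.20 ± 0.09 and 0.06 ± 0.09 in hippocampus (n = 4 each). Vehicle groups were spread. In hippocampus the AD vehicle group, labelled with 2 copies, averaged 0.57 ± 0.38, near the 0.51 ± 0.52 of Polb vehicle. Its highest array (0.89) lay below the lowest WT vehicle array (1.09), and the AD NR group averaged 0.94 ± 0.32. The array labelled Polb vehicle 4 of cortex (1.42), the array labelled ADPolb vehicle 2 of cortex (1.23), the array labelled Polb vehicle 3 of hippocampus (1.25) and the array labelled ADPolb vehicle 1 of hippocampus (1.08) lay at or above the mean of arrays with 2 copies in their own region (1.22 in cortex, below 1.08 in hippocampus). Conversely, the arrays labelled AD vehicle 1 lay at 0.39 in cortex and 0.03 in hippocampus, below the heterozygote means of these regions (0.48 and 0.29). Arrays nearer to the mean of the other label than to that of their own numbered 9, these included. These 6 arrays go against their Polb label, and any direction drawn below from vehicle AD, Polb or ADPolb groups includes them. The position of the Polb probe relative to the deleted part of the gene is not given in the sources used here. Within a region Polb passed no genotype comparison: it differed by -0.50 ± 0.25 (adjusted p = 0.236) in Polb cortex, -0.58 ± 0.29 (0.241) in ADPolb cortex, -0.73 ± 0.22 (0.224) in Polb hippocampus and -0.70 ± 0.27 (0.213) in ADPolb hippocampus, each against WT vehicle with n = 4.

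**Figure D1:**
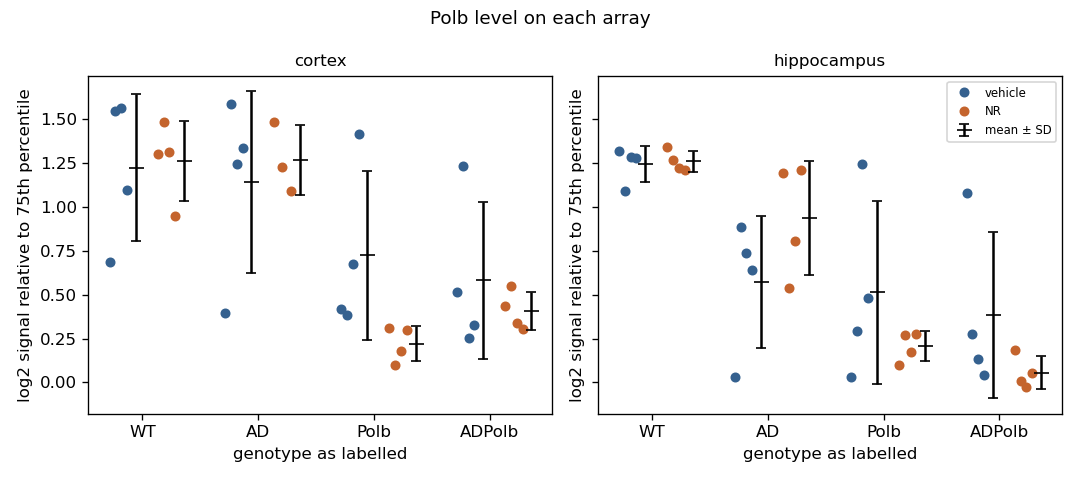
Polb level on each array (points, vehicle in blue and NR in orange) with group mean and SD (bars) for cortex and hippocampus; the vertical axis is log2 intensity relative to the array's 75th percentile. The NR-treated heterozygote groups of hippocampus average 0.20 and 0.06 while both WT groups average 1.24 and 1.26. The AD groups of hippocampus, labelled with 2 copies, average 0.57 with vehicle and 0.94 with NR, and the Polb vehicle group averages 0.51. In all, 6 vehicle arrays lie at or past their region's mean of the other Polb label.

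Thy1, whose regulatory cassette drives the human APP and tau transgenes of 3xTgAD, was higher in AD and ADPolb arrays over both regions, at 8.03 ± 0.67 (n = 32) against 7.06 ± 0.29 (n = 32), a rise of 0.97 ± 0.16 (adjusted p = 6.85e-06). In hippocampus vehicle arrays it rose by 2.07 ± 0.37 in AD (adjusted p = 0.00382) and by 2.05 ± 0.37 in ADPolb (adjusted p = 0.00413) with the sex term, while the group means were 8.69 ± 0.37 and 8.67 ± 0.49 against 7.13 ± 0.11 in WT. The array labelled ADPolb NR 4 of hippocampus stood at 7.12, which goes against its AD label. The mouse App and Mapt probes differed by -0.06 ± 0.11 (adjusted p = 0.812) and 0.18 ± 0.09 (0.26) between carriers and non-carriers. Eif2s3y and Ddx3y on the Y chromosome matched the labelled sex on all arrays but 3. There Eif2s3y was expressed although the label says female: WT vehicle 3 of cortex (2.66), WT vehicle 2 of hippocampus (2.29) and Polb NR 2 of hippocampus (2.30).

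The largest contrast in the data was between regions, with 2450 genes higher and 2786 lower in hippocampus among 16303 tested. Fibcd1, a marker of hippocampal CA1 neurons, was higher by 4.06 ± 0.29 (adjusted p = 5.74e-18), Dsp, a marker of the dentate gyrus, by 5.01 ± 0.36 and Spink8 by 4.72 ± 0.28 (n = 32 against 32). Adora2a, which marks striatal medium spiny neurons, was lower (-3.08 ± 0.44). Of 16 markers of hippocampal fields 11 rose and 1 fell, over all genes as well as adjusted over the list alone (camera adjusted p = 2.1e-11; adjusted p = 0.029 with an estimated correlation). Of 19 markers of choroid plexus, the tissue that secretes cerebrospinal fluid, 18 rose, and all 10 ependymal markers did, with a median of 2.81 and 1.71 (adjusted p = 6.1e-09 and 6.1e-08; 0.28 and 0.24 with an estimated correlation). Of 23 reactive astrocyte genes 13 rose, among them Gfap, the astrocyte intermediate filament (1.33 ± 0.15), and Serpina3n (2.61 ± 0.34). Of 26 disease-associated microglia genes 15 rose, among them Gpnmb (2.05 ± 0.26), and of 16 complement genes 9 rose (12 adjusted over the list alone), C4b by 1.67 ± 0.23. These lists had adjusted p-values of 2.5e-07, 2.2e-06 and 0.00052, and of 0.24, 0.24 and 0.26 with an estimated correlation. General astrocyte markers held 3 rises and 3 falls of 18 (adjusted p = 0.61). Among NAD metabolism genes 8 of 25 rose and 1 fell, with Cd38, which encodes the main NAD-consuming ectoenzyme, at 1.28 ± 0.17 and Naprt at 0.65 ± 0.11. The sirtuin gene Sirt1 fell by 0.35 ± 0.07 (adjusted p = 0.000113). The NAD list passed at an adjusted p of 0.01 and at 0.24 with an estimated correlation. Markers of striatum fell for 11 of 13 members (12 adjusted over the list alone; adjusted p = 2e-08, and 0.24 with an estimated correlation).

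To ask what the AD transgenes do in untreated animals, AD vehicle cortex was set against WT vehicle cortex (n = 4 each). Here 353 genes rose and 501 fell of 15957. Gdpd3, a lysophospholipase D, rose by 5.15 ± 0.45 (adjusted p = 1.31e-07), Ankrd33b by 4.66 ± 0.69 (0.000316) and Npw, a neuropeptide precursor, by 3.71 ± 0.34 (2.19e-07). Mroh4 was at least 9.55-fold higher. The falls included Isl1, a transcription factor of striatal cholinergic and other neurons (-4.03 ± 1.09), the vasopressin gene Avp (-3.88 ± 0.97) and Baiap3 (-3.66 ± 0.79). Excitatory neuron markers rose in 6 of 18 cases (7, with 1 fall, adjusted over the list alone), among them Neurod2 (1.91 ± 0.34), Fezf2 (2.63 ± 0.56) and Neurod6 (2.61 ± 0.56). That list had an adjusted p of 0.013 and of 0.59 with an estimated correlation. Nampt, the rate-limiting enzyme of NAD salvage, fell by 0.92 ± 0.22 and the nucleoside transporter Slc29a1 by 0.85 ± 0.18 among 24 NAD metabolism genes (median -0.57; adjusted p = 0.022, and 0.59 with an estimated correlation). The repair endonuclease gene Apex1 fell by 0.86 ± 0.18 (adjusted p = 0.00849), the p53 target Ccng1 rose by 1.26 ± 0.31, and Casp1, the inflammasome protease, rose by 1.55 ± 0.36. Of 57 genes of oxidative phosphorylation 2 rose, Sdhb (1.15 ± 0.23) and Cox7c (1.24 ± 0.31), and of 16 glucocorticoid response genes 4 rose, including Zbtb16 (1.63); both lists were at 0.59 with an estimated correlation, after 0.019 and 0.04 without it. Of 21 cholesterol synthesis genes Fdps (0.81 ± 0.21) and Stard4 (0.86 ± 0.23) rose (adjusted p = 0.019, and 0.59 with an estimated correlation); Stard4 turned to -0.31 with the mean of all its probes. None of the 23 oligodendrocyte genes passed over all genes, although the list lay higher (median 0.50, adjusted p = 0.019, and 0.69 with an estimated correlation).

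Striatal markers moved with this comparison. All 13 members were lower in AD vehicle cortex with a median of -2.14 (adjusted p = 0.00019, and 0.59 with an estimated correlation); 1, Gpr6 (-1.76 ± 0.44), fell over all genes and 10 did so adjusted over the list alone. The marker score was 1.80 ± 0.34 (SD, n = 4) in WT vehicle cortex, 0.05 ± 1.17 in AD vehicle, -0.53 ± 0.55 in Polb vehicle and -1.05 ± 0.74 in ADPolb vehicle. With that score as a covariate the calls against WT numbered 96 for AD, 8 for Polb and 72 for ADPolb. The score follows the groups, and the called differences kept most of their size: their median was 0.90 instead of 1.13 for AD and 0.81 instead of 1.06 for ADPolb, while the median SE went from 0.28 to 0.31 and from 0.26 to 0.34. The count of 854 for AD was 222, 334 and 281 without AD vehicle arrays 1, 3 and 4 and 557 without WT vehicle array 3. It was 320 without the 5 doubted cortex arrays, a set chosen after the data were seen, and 1681 without the array of non-uniform spots, which shares the fit. Without that array, a choice made after the data were seen, the striatum list passed again (adjusted p = 0.00015, and 0.70 with an estimated correlation), and the 6 other lists did not, with adjusted p-values from 0.056 to 0.092.

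**Figure D2:**
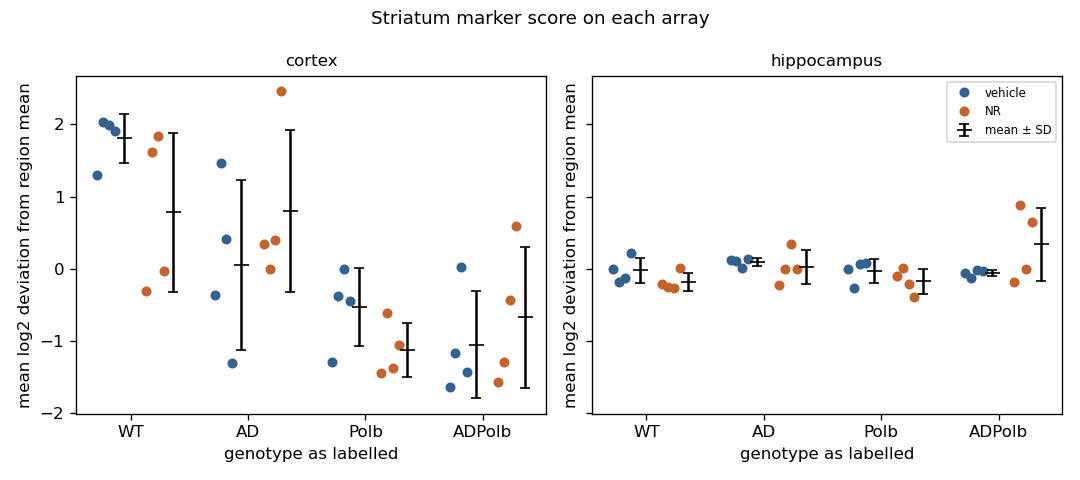
Mean log2 deviation of striatal marker genes from the region mean on each array (points, vehicle in blue and NR in orange), with group mean and SD (bars), in cortex and hippocampus. In cortex the WT vehicle group stands at 1.80 and the ADPolb vehicle group at -1.05; in hippocampus the group means lie between -0.18 and 0.34.

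Loss of 1 Polb copy was asked about in the same way. In Polb vehicle cortex 394 genes rose and 689 fell against WT vehicle (n = 4 each). Glp2r rose by 4.12 ± 1.01 (adjusted p = 0.0163), Thbs4 by 3.59 ± 0.84 and Serinc2 by 3.66 ± 0.86. Genes that fell included Lhx8 (-6.21, adjusted p = 0.0153), a transcription factor of forebrain cholinergic neurons, Calcr, the calcitonin receptor (-4.99 ± 1.01), and Isl1 (-4.50 ± 0.96). The neuropeptide gene Ucn3 was at least 22.5-fold lower. All 13 striatal markers fell adjusted over the list alone and 8 over all genes, among them Drd2 (-3.17 ± 0.80), Ppp1r1b (-2.24 ± 0.60) and Pde10a (-1.93 ± 0.56). The list had an adjusted p of 3.0e-08 and of 0.34 with an estimated correlation. Excitatory neuron markers rose in 6 of 18 cases and fell in 1 (7 and 2 adjusted over the list alone; adjusted p = 0.0021, and 0.32 with an estimated correlation). Immediate early genes, the first transcribed after neuronal activity, were higher in 23 of 24 cases, of which 1, Dusp6 (1.13 ± 0.24), passed (adjusted p = 0.0021, and 0.60 with an estimated correlation). The uracil glycosylase gene Ung fell by 1.02 ± 0.28 (adjusted p = 0.027) and Apex1 by 0.56 ± 0.16, 2 of 23 base excision repair genes, a list that did not pass (adjusted p = 0.571). Cd38 fell by 1.04 ± 0.30, Nt5e by 1.28 ± 0.37 and Slc29a1 by 0.59 ± 0.16, whereas Ccng1 rose by 1.30 ± 0.27, Casp1 by 1.33 ± 0.32 and App by 0.78 ± 0.23 (adjusted p = 0.0404). Of the oxidative phosphorylation genes 3 rose, Sdhb (0.89), Ndufc2 (1.47) and Ndufa4 (0.61), with an adjusted p of 0.026 (0.051 without the array of non-uniform spots) and of 0.53 with an estimated correlation. Of 7 lymphocyte genes 1, Cd3e, fell by 0.60 ± 0.16 (list 0.026, and 0.32 with an estimated correlation). The count of 1083 was 559 without WT vehicle array 3, 590, 477, 414 and 551 without Polb vehicle arrays 1 to 4 in turn, and 464 without the doubted arrays. Conversely, it was 2529 with normexp, 1912 without the filter on dim probes and 2160 without the array of non-uniform spots. With quantile normalization 49.6% of calls were rises, compared with 36.4% here.

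With both changes combined, ADPolb vehicle cortex had 365 genes higher and 521 lower than WT vehicle (n = 4 each). Ankrd33b rose by 4.83 ± 0.69, Gdpd3 by 4.74 ± 0.45 (adjusted p = 2.48e-07), Ocel1 by 3.56 ± 0.25 (1.11e-09), Npw by 3.39 ± 0.34 and Prg4 by 3.80 ± 0.92, and Slc22a2 was at least 15.3-fold higher. Genes of striatal neurons were among the falls: Lhx8 (-7.32 ± 1.67), Isl1 (-5.25 ± 1.09), the adenosine receptor gene Adora2a (-5.01 ± 1.16), the dopamine receptor gene Drd2 (-4.98 ± 0.90, adjusted p = 0.00223) and Slc5a7, the choline transporter (-4.48 ± 1.08). Of the 13 striatal markers 10 fell (12 adjusted over the list alone; median -3.06, adjusted p = 9.6e-11, and 0.33 with an estimated correlation). Meningeal and fibroblast markers were higher in 14 of 15 cases, 1 of them, Islr (2.21 ± 0.49), past the threshold and 5 adjusted over the list alone (adjusted p = 5.3e-05, and 0.44 with an estimated correlation). Excitatory neuron markers included 4 rises and 1 fall (6 and 1 adjusted over the list alone), led by Neurod2 (2.16 ± 0.34), at an adjusted p of 0.0033 and of 0.33 with an estimated correlation. Glucocorticoid response genes held 3 rises, among them Map3k6 (1.23), and immediate early genes 1 rise with 20 of 24 positive (adjusted p = 0.0043 and 0.0033; 0.33 and 0.55 with an estimated correlation). Nampt fell by 1.02 ± 0.22 (adjusted p = 0.00946) and Cd38 by 1.32 ± 0.34. Apex1 fell by 0.77 ± 0.18 while Mbd4, a thymine glycosylase gene, rose by 0.83 ± 0.25. Casp1 rose by 1.70 ± 0.36 and Nos2 fell by 0.70 ± 0.16. The lists called against WT overlapped: 216 genes were higher and 272 lower in AD as well as ADPolb (8.07 and 16.4 for independent lists), 184 and 287 in Polb as well as ADPolb (9.01 and 22.5), and 198 and 271 in AD as well as Polb (8.72 and 21.6). Part of that excess may come from the WT vehicle arrays that all 3 comparisons share. With quantile normalization 50.6% of these calls were rises, compared with 41.2% here, and for AD against WT 48.1%, compared with 41.3%. The count of 886 was 1367 and 583 without WT vehicle arrays 1 and 2, and 320, 553 and 545 without ADPolb vehicle arrays 1, 2 and 4. It was 1665 without the array of non-uniform spots, which shares the fit.

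On the AD background, loss of a Polb copy passed for no gene in cortex. Between ADPolb and AD vehicle arrays limma called 0 of 15957 genes, with 597 at an unadjusted p under 0.05. The smallest p-values belonged to complement C2 (1.08 ± 0.24), Zim3 (-1.24), Ptgdr (1.68), Tspan8 (2.30) and Tbrg4 (-0.79), none of which passed. Oligodendrocyte and myelin genes were lower in 21 of 23 cases (0 past the threshold, 6 falls adjusted over the list alone; median -0.79), with an adjusted p of 4.6e-19 and of 0.12 with an estimated correlation. All 15 meningeal markers were higher (7 rises adjusted over the list alone; median 1.03), with an adjusted p of 1.8e-13 and again 0.12 with an estimated correlation. Striatal markers lay lower (median -0.92) and adult neurogenesis genes higher (0.26), at 3.9e-08 and 0.0022 before and 0.39 and 0.18 with an estimated correlation.

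In hippocampus the AD transgenes were accompanied by 61 higher and 35 lower genes in AD vehicle against WT vehicle arrays (n = 4 each, 15965 tested). All 4 WT vehicle arrays are labelled female and all 4 AD and all 4 ADPolb vehicle arrays male, so that these comparisons rest on a sex difference estimated from the other groups. The count of 96 was 629 without the sex term and 196 with sex taken from the arrays. Gdpd3 rose by 4.27 ± 0.39 (adjusted p = 2.16e-07), Ankrd33b by 4.04 ± 0.66, Ocel1 by 3.66 ± 0.26 (3.23e-09) and Ttll2 by 3.51 ± 0.59, and Dcstamp was at least 11.7-fold higher. Cthrc1, a secreted collagen triple helix protein, was at least 16.3-fold lower and Ppcdc at least 9.75-fold lower; the Wnt receptor gene Fzd6 fell by 2.99 ± 0.55. The DNA damage kinase gene Atm fell by 1.51 ± 0.27 (adjusted p = 0.0039) and Nampt by 0.78 ± 0.14 (adjusted p = 0.00357). Genes of disease-associated microglia, the state described around amyloid plaques, were higher in 22 of 26 cases with a median of 0.52. None rose over all genes and 8 rose adjusted over the list alone; among the values were Cst7 (4.21 ± 1.04, adjusted p = 0.0614), Itgax (2.92 ± 0.85) and Trem2 (1.31 ± 0.42). That list had an adjusted p of 0.0006 and of 0.99 with an estimated correlation. The choroid plexus score was -1.62 ± 0.91 (SD, n = 4) in WT vehicle, 0.24 ± 1.29 in AD vehicle and 0.20 ± 2.66 in ADPolb vehicle hippocampus, and the ependyma score -1.01 ± 0.24, -0.34 ± 1.27 and -0.11 ± 1.47. With the choroid plexus score as a covariate 139 genes were called for AD and 169 for ADPolb. Oxidative phosphorylation genes were higher in 49 of 57 cases (median 0.31; 1.3e-06, and 0.99 with an estimated correlation), and markers of hippocampal fields were lower in 14 of 16 (median -1.27; 0.0047, and 0.99 with an estimated correlation). Immediate early genes lay lower (median -0.55, 0.026, and 0.99 with an estimated correlation). Without AD vehicle array 1, which goes against its Polb label, the count was 601; it was 59 without WT vehicle array 4, 57 and 56 without AD vehicle arrays 2 and 3, and 177 without the 5 doubted hippocampus arrays.

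Polb heterozygosity alone gave 23 falls and 0 rises in vehicle hippocampus by limma, with 1492 genes at an unadjusted p under 0.05. The count depends on the processing: it was 0 with normexp, 3 with quantile normalization (33.3% of them rises), 316 without the filter on dim probes and 419 in a fit of only these groups. The taste receptor gene Tas2r104 was at least 7.81-fold lower, Ino80e, a chromatin remodelling subunit gene, at least 7.50-fold, Zdhhc25 at least 7.25-fold and Rhox3e at least 7.13-fold; each of these probes was well above background in WT arrays alone. Shank2, a postsynaptic scaffold gene, fell by 1.43 ± 0.30 (adjusted p = 0.0417), 1 of 31 synapse genes (2 adjusted over the list alone; list 0.00038, and 0.33 with an estimated correlation). Many lists lay higher without a called member: disease-associated microglia genes in 25 of 26 cases (median 0.66; 2 rises adjusted over the list alone), oligodendrocyte genes in 22 of 23 (0.67), complement genes in 16 of 16 (0.51) and inflammatory genes in 22 of 26 (0.43). Their adjusted p-values were 2.1e-13, 6.6e-10, 9.6e-06 and 2.9e-08, and became 0.26, 0.28, 0.28 and 0.26 with an estimated correlation. Itgax (2.19 ± 0.68), Cd52 (1.48 ± 0.46), Ccl3 (1.89 ± 0.57) and C4b (1.41 ± 0.53) were among them, and none passed. Blood genes were higher as well, 7 of 7 adjusted over the list alone (median 1.69; 1.1e-06, and 0.28 with an estimated correlation), and choroid plexus markers in 18 of 19 cases (median 1.98; 3e-05, and 0.50 with an estimated correlation). Ssty1, of a family on the Y chromosome, was among the falls, and 1 of the WT vehicle arrays is labelled female with Eif2s3y expressed. The blood score of the 4 Polb vehicle arrays ran from -0.60 to 4.14, and with the blood or the choroid plexus score as a covariate 0 genes were called. In all, 18 of the 44 lists passed, and none did so with an estimated correlation. Leaving out any one of the 8 arrays brought the count of 23 to between 0 and 9, and 1 gene was called without the doubted arrays.

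In ADPolb vehicle hippocampus 57 genes rose and 84 fell against WT vehicle (n = 4 each). Gdpd3 (4.05 ± 0.39), Ankrd33b (4.18 ± 0.66), Ocel1 (3.50 ± 0.26), Zfp963 (2.75 ± 0.34) and the chemokine gene Ccl17 (2.64 ± 0.38) rose, and Cthrc1, Ppcdc and Olfr288 were at least 13.6-fold, 8.73-fold and 6.61-fold lower. The checkpoint kinase gene Chek2 was at least 4.07-fold lower, Atm fell by 1.13 ± 0.27 (adjusted p = 0.0434) and Nampt by 0.63 ± 0.14 (0.0242), whereas Nos2, the inducible nitric oxide synthase gene, rose by 1.02 ± 0.20 (0.00845) and Mvk, mevalonate kinase, by 1.03 ± 0.14 (9.72e-05). Mvk was the 1 of 21 cholesterol synthesis genes that passed (2 rises and 1 fall adjusted over the list alone; list 0.0081, and 0.97 with an estimated correlation). Oxidative phosphorylation genes were higher in 52 of 57 cases and disease-associated microglia genes in 23 of 26, with medians of 0.33 and 0.53 and no called member (5.4e-08 and 7.1e-05; both 0.97 with an estimated correlation). AD and ADPolb shared 36 higher and 25 lower genes against WT (0.218 and 0.184 for independent lists), and Polb and ADPolb shared 5 lower ones (0.121); part of the excess may come from the shared WT vehicle arrays. The share of rises was 40.4% here and 62.4% with normexp or 62.0% with quantile normalization. The count of 141 was 90, 80 and 75 without WT vehicle arrays 1, 2 and 4, 84 without ADPolb vehicle array 2, 62 without the doubted arrays, 618 without the sex term and 311 with sex taken from the arrays.

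Against AD vehicle hippocampus, ADPolb vehicle arrays had 2 higher and 21 lower genes; chance is not excluded, as 2 of 35 splits had as many. Tra2b, a splicing regulator, rose by 0.97 ± 0.17 (adjusted p = 0.00982) and Nos2 by 0.85 ± 0.16 (0.0153). The falls were mostly at the floor: Vmn1r67 was at least 10.2-fold, Olfr876 at least 6.61-fold and the titin gene Ttn at least 6.18-fold lower. Endothelial and mural cell genes were higher in 21 of 24 cases with no called member (median 0.19; 0.032, and 0.95 with an estimated correlation). The count of 23 was 37, 2 and 10 without AD vehicle arrays 1, 2 and 3, and 6, 4 and 92 without ADPolb vehicle arrays 1, 3 and 4. It was 0 without the doubted arrays, and 10 with quantile normalization, where 40% of calls were rises against 8.70% here.

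In the fit over all slides, with the slide as a random block, 367 genes were higher and 582 lower in the 32 carrier arrays than in the 32 others. The block used 1 correlation for all genes (0.0952). Its p-values therefore rest more on the spread between arrays than on that between the 8 slides. Gdpd3 rose by 4.95 ± 0.21 (adjusted p = 2.56e-28), Ocel1 by 3.11 ± 0.13 (3.36e-29), Bricd5 by 2.26 ± 0.11, Zfp963 by 2.72 ± 0.15, the formyl peptide receptor gene Fpr2 by 2.22 ± 0.25 and Ccl17 by 2.06 ± 0.16. The falls included Samd4 (-3.89 ± 0.45), Cthrc1 (-3.58 ± 0.22, adjusted p = 8.16e-21), Fzd6 (-2.41 ± 0.20) and the cartilage collagen gene Col2a1 (-2.09 ± 0.16), and Ppcdc was at least 8.50-fold lower. Among DNA damage genes Atm (adjusted p = 6.3e-06), Chek2 (-0.94 ± 0.26) and Rrm2b (-0.52 ± 0.16) fell; in base excision repair Apex1 fell by 0.30 ± 0.09 and Mbd4 rose by 0.45 ± 0.13. Nampt fell by 0.49 ± 0.09 (adjusted p = 0.000203). Of 57 oxidative phosphorylation genes 3 rose (4 adjusted over the list alone), Cox7c (0.58 ± 0.14), Sdhb (0.48 ± 0.12) and Ndufa2 (0.30 ± 0.10), with an adjusted p of 0.0095 and of 0.98 with an estimated correlation. Cst7, a cystatin of activated microglia, rose by 1.32 ± 0.42 (adjusted p = 0.0438) as the 1 of 26 disease-associated microglia genes that passed (2 adjusted over the list alone; list 0.022, and 0.98 with an estimated correlation). Of 21 cholesterol synthesis genes Mvk (0.54 ± 0.09) and Stard4 (0.43 ± 0.14, but -0.22 with the mean of its probes) rose, and 6 rose with 1 fall adjusted over the list alone (0.046, and 0.98 with an estimated correlation). The count of 949 was 390 with normexp, 216 with 1 mean per slide and 109 in vehicle arrays alone. Called genes lay next to each other on chromosomes in 120 pairs, where the highest of 10000 random sets was 85. Stretches of chromosome carried with the transgenes or from another strain may therefore account for part of these calls. Which of the genes named here lie in such stretches was not examined.

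The same fit gave 15 higher and 363 lower genes in the 32 Polb heterozygote arrays. Besides Polb, Ung fell by 0.44 ± 0.11 (adjusted p = 0.0258), 2 of 23 base excision repair genes, and the list did not pass (0.205). Gins4, a DNA replication factor gene, rose by 0.51 ± 0.08 (adjusted p = 0.000407), Gjb6, an astrocyte connexin gene, by 0.55 ± 0.14 and Dcc by 0.63 ± 0.16. Gins4 lies 8 tested genes from Polb on chromosome 8, so a stretch of chromosome carried with the targeted allele is not excluded for it. Many falls were in genes of low signal, such as Mhrt (-1.56 ± 0.32), Cmah (-1.38 ± 0.31), Olfr1153 (-1.45 ± 0.31) and Gys2 (-1.40 ± 0.31). Fallen genes had a median level of -4.13, compared with 0.22 over all tested genes. Striatal markers were lower in 13 of 13 cases, Gpr6 (-0.73 ± 0.19) and Pde10a (-0.82 ± 0.22) past the threshold and 10 adjusted over the list alone (median -0.82; 9.3e-09, and 0.55 with an estimated correlation). Meningeal markers were higher in 15 of 15 cases and immediate early genes in 21 of 24, with no called member (medians 0.50 and 0.22; 0.00033 and 0.0032, both 0.63 with an estimated correlation). The count of 378 was 3 with normexp, where 33.3% of calls were rises against 3.97% here, and 75 with quantile normalization (16%). With 1 mean per slide limma called 0 genes, and without the doubted arrays 147.

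NR was asked about within each slide, on which vehicle and NR arrays held separate lines of positions. In WT cortex 98 genes rose and 102 fell with NR (n = 4 against 4), but 17 of the 35 ways to split these arrays into groups of 4 gave at least as many calls, so chance is not excluded for this count or for the genes named from it. Markers of excitatory projection neurons rose in 4 of 18 cases (7, with 1 fall, adjusted over the list alone), among them Neurod6 (2.18 ± 0.50, adjusted p = 0.0318), Fezf2 (2.06 ± 0.50) and Nptx1 (1.57 ± 0.39). That list had an adjusted p of 0.00063 and of 0.22 with an estimated correlation. Myh3 rose by 3.34 ± 0.70, and Pkp1 and Adamts13 were at least 10.7-fold and 6.13-fold higher. Among the falls were Arhgap36 (-5.05 ± 1.26), Prok2 (-3.08 ± 0.73) and Ucn3, which was at least 11.7-fold lower. Cd38 fell by 1.18 ± 0.30 (adjusted p = 0.0486), the 1 of 24 NAD metabolism genes that passed (list median -0.27; 0.014, and 0.40 with an estimated correlation). C1ql1 fell by 1.44 ± 0.37 among 10 oligodendrocyte precursor genes (4 adjusted over the list alone; 0.011, and 0.40 with an estimated correlation). Synapse genes were higher in 24 of 31 cases (0 passed, 3 adjusted over the list alone; 0.00088, and 0.18 with an estimated correlation). Striatal markers were lower in 13 of 13 cases with no called member (median -1.10; 0.0018, and 0.66 with an estimated correlation). The score of these arrays was 0.78 ± 1.10 after 1.80 ± 0.34 with vehicle, and with it as a covariate 38 genes were called (median size of the 200 differences 0.90 instead of 0.97). The count of 200 was 37 with normexp, 15 in a fit of only the 8 arrays compared, and 340 without the doubted arrays. It was 525 without WT vehicle array 4, 324 and 361 without WT NR arrays 2 and 3, and 545 without the array of non-uniform spots, which shares the fit.

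In the other cortex groups limma called 0 genes for NR in AD, Polb and ADPolb, with 780, 193 and 225 at an unadjusted p under 0.05, and 0 for the mean over genotypes, with 1041. The smallest p in that mean belonged to Ntng2 (0.80 ± 0.16, adjusted p = 0.33), Rab39 (-0.91) and Yme1l1 (-0.54). Heat shock genes were lower in 12 of 14 cases over genotypes, with Dnajb1 at -0.35 ± 0.11 and Bag3 at -0.27 ± 0.09 (0 falls over all genes, 3 adjusted over the list alone; 0.00087, and 0.19 with an estimated correlation). Reactive astrocyte genes were lower in 17 of 20 cases, Serpina3n at -0.93 ± 0.37, and NAD metabolism genes in 22 of 24, Cd38 at -0.40 ± 0.15 and Nampt at -0.24 ± 0.10 (0.00087 and 0.0052, both 0.27 with an estimated correlation). The NAD metabolism score of the AD NR array of non-uniform spots was -2.15, and the 3 other arrays of its group lay between -0.13 and 0.08. Without that array, a fit added after the data were seen, 19 of 24 were lower with a median of -0.05 instead of -0.15 (adjusted p = 0.018, and 0.12 with an estimated correlation). Cd38 and Nampt have no value on it and stayed as given. The reactive astrocyte score of that array was -1.82, and the 3 others of its group lay between -0.39 and -0.21. Its heat shock score was -0.54, and the 3 others lay between -0.16 and -0.14. The values given for these lists include that array. Synapse genes were higher in 27 of 31 cases with a median of 0.09 (0.0025, and 0.19 with an estimated correlation). The F test of whether the NR response differed between genotypes called 4 genes, named here after their values were seen: Camk4, a calcium-dependent kinase gene, Efcab15 and Zbtb22 at an adjusted p of 0.0448 and Fam98b at 0.0477; as many were called in 32 of 100 splits. In WT cortex the NR difference was -1.12 for Camk4, -1.03 for Efcab15 and 1.49 for Zbtb22, and in the other genotypes all 4 lay between -0.23 and 0.32.

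In hippocampus NR passed for no gene in any genotype. Limma called 0 genes in WT, AD, Polb and ADPolb, with 271, 299, 854 and 1310 at an unadjusted p under 0.05, 0 over genotypes with 789, and 0 for a difference between genotypes with 621. The gene with the smallest p over genotypes was Adm, the adrenomedullin gene, at -0.79 ± 0.15 (adjusted p = 0.238, n = 16 against 16). Immediate early genes were lower with NR in 22 of 23 cases (median -0.43). None passed over all genes, while 10 fell adjusted over the list alone, Egr2 (-1.46 ± 0.34), Fos (-1.27 ± 0.34), Egr1 (-0.63 ± 0.19), Nr4a1 (-0.73 ± 0.22) and Arc (-0.70 ± 0.26) among them. The list had an adjusted p of 3.2e-14 and of 0.10 with an estimated correlation, and 0.054 with fry. Its score was 0.54 ± 0.32 (SD, n = 4) with vehicle and -0.23 ± 0.05 with NR in WT, and 0.39 ± 0.40 and -0.37 ± 0.11 in Polb, whereas in AD and ADPolb the groups overlapped. Glucocorticoid response genes were lower in 16 of 16 cases (median -0.19; 0 fell, 1 adjusted over the list alone; 1.1e-05, and 0.52 with an estimated correlation), and ependymal genes were higher in 10 of 10 (median 0.54; 9.4e-06, and 0.94 with an estimated correlation). Within Polb, 20 lists passed and none with an estimated correlation. Blood genes were lower in 7 of 7 cases (median -1.66), interferon response genes in 32 of 33 (-0.54) and oligodendrocyte genes in 21 of 23 (-0.76), at 1.5e-06, 5.2e-10 and 5.6e-12 (all 0.30 with an estimated correlation). The blood scores were 2.10 and 4.14 on vehicle arrays 1 and 2, and from -0.60 to -0.00 on the 2 other vehicle arrays and -0.60 to -0.22 on the NR arrays. In ADPolb the smallest p-values belonged to Map2k7 (0.88 ± 0.17), Syce1 (-2.05 ± 0.43) and the oxytocin gene Oxt (4.35 ± 0.99, with an SD of 3.53 among the 4 NR arrays), at adjusted p-values of 0.50, 0.508 and 0.574. The 7 sirtuin genes passed as a list in none of the comparisons made, with 0.383 as the smallest adjusted p.

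**Figure D3:**
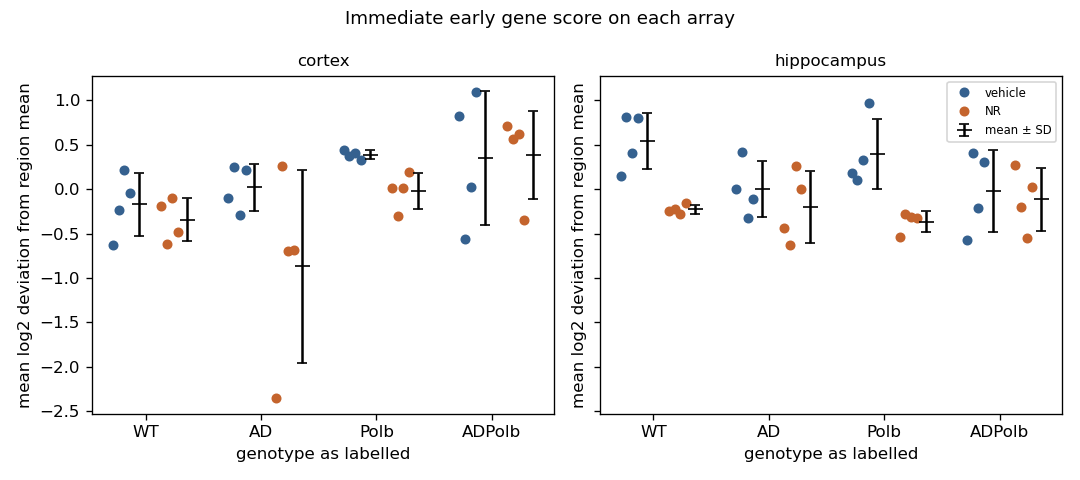
Mean log2 deviation of immediate early genes from the region mean on each array (points, vehicle in blue and NR in orange) with group mean and SD (bars) in cortex and hippocampus. In hippocampus the WT groups average 0.54 with vehicle and -0.23 with NR and the Polb groups 0.39 and -0.37, while the AD groups average -0.00 and -0.20.

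Whether NR moved genes back toward WT was asked of the genes called in ADPolb vehicle against WT vehicle. In cortex the NR effect in ADPolb had the opposite sign for 605 of 886 genes and correlated with the ADPolb effect at r = -0.527 across genes, which are not independent replicates. Simulated unchanged groups that share the ADPolb vehicle arrays in the same way gave -0.513 on average. The covariance over these genes was -0.275, compared with -0.0648 in the simulation. With the 4 shared arrays split into 2 and 2, r averaged -0.353 over 6 splits, between -0.659 and 0.120, and -0.0992 where each split made its own calls, with covariances of -0.220 and 0.00333. In hippocampus 104 of 141 genes had the opposite sign, with r = -0.519 against -0.505 simulated, a covariance of -0.416 against -0.0503, and -0.414 with split arrays (-0.0854 with its own calls, covariance -0.0414). Over all genes tested r was -0.259 in cortex and -0.327 in hippocampus, while the simulation gave -0.515 and -0.503. The covariance over all genes was -0.0445 in cortex against -0.0664 simulated, and -0.0730 in hippocampus against -0.0605. The simulation was read over the genes called in the real data, so over called genes it lacks the selection that calling brings. Its covariance there is no fair baseline and decides nothing. Over all genes the covariance went past the simulated one in hippocampus but not in cortex. Where each split made its own calls, r averaged -0.0992 in cortex and -0.0854 in hippocampus. A move back toward WT was therefore not shown in either region.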

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

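In this part, the test of whether the AD carrier effect differs between regions and the fits without doubted arrays were chosen only after the results were seen.

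On the first AD NR array of cortex, the array with 26764 non-uniform spots, Thy1 stood at 6.64 where the nearest array of its group had 7.51, and App at 5.08 where the nearest had 6.60. App also stood apart on the first AD NR array of hippocampus, at 6.45 with the nearest at 6.76. Ttr, the transthyretin gene of choroid plexus, stood apart on 4 arrays: Polb vehicle 1 of cortex (0.63, nearest 2.42), Polb NR 2 of cortex (8.04, nearest 2.56), ADPolb vehicle 1 of cortex (-3.26, nearest 2.76) and Polb NR 3 of hippocampus (3.36, nearest 7.86). The 75th percentile of intensity was 770 on AD vehicle array 1 of hippocampus and 451 on the nearest array of that group. Such a distance was found in 8 of 126 groups, and chance gives about 1 group in 20.

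A response to NR that differed between genotypes in cortex was called by limma for Camk4, Efcab15 and Zbtb22 (adjusted p = 0.0448 each) and for Fam98b (0.0477). As many genes were called in 32 of 100 splits of the cortex arrays, with 54 as the highest, so chance is not excluded for these 4. The AD carrier effect differed between regions for 3 genes: Dcstamp (3.05 ± 0.51, higher in hippocampus, adjusted p = 0.00204), Mapk1ip1l (-0.83 ± 0.16, 0.0405) and Matn2 (-1.27 ± 0.26, 0.0431); for Thy1 the difference was 0.84 ± 0.26 (0.367).

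The cortex genes called against WT vehicle arrays moved with striatal markers, which were high in those arrays. Striatal tissue in the cortex samples would predict that these genes follow the striatum score within the other groups, and across genes, which are not independent replicates, the median correlation over 4 comparisons was -0.757. Scores shuffled among arrays reached -0.779, -0.822, -0.734 and -0.828, lower than the real values of -0.720, -0.794, -0.694 and -0.823, so the test decides nothing. With the striatum score as a covariate, the counts for AD, Polb, ADPolb and NR in WT were 96, 8, 72 and 38 instead of 854, 1083, 886 and 200, and they were 677, 964, 793 and 164 with a choroid plexus score. The striatum score, unlike the choroid plexus one, follows the split between WT vehicle and the other arrays, so adding it can end calls whatever the cause, and this comparison decides nothing either. The called differences kept most of their size under it, with medians of 0.90, 0.71, 0.81 and 0.90 and median SEs of 0.31, 0.30, 0.34 and 0.22, where the SEs had been 0.28, 0.25, 0.26 and 0.21 and the medians 1.13 for AD, 1.06 for ADPolb and 0.97 for NR in WT. The score also varied within groups of one genotype, from -0.30 to 1.84 among WT NR arrays and from -0.00 to 2.46 among AD NR arrays. Dissection that took in more striatum on the WT vehicle arrays is a candidate explanation. For AD, Polb and ADPolb it cannot be told apart from a difference of genotype, since each genotype holds 1 slide. For NR in WT both groups share slide and, by label, genotype, so a labelled difference of genotype is not the cause there. NR, position on the slide and chance stay open beside dissection. The WT vehicle arrays of cortex also correlated least with the other cortex arrays, the array of non-uniform spots aside. Their median correlations ran from 0.955 to 0.964, those of WT NR from 0.966 to 0.972 and those of the other genotypes from 0.971 to 0.984. WT vehicle arrays 3 and 4 had the lowest 75th percentiles of all arrays (373 and 348). Whether array quality adds to the calls against WT was not tested.

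Genes called in AD carriers could come from slides rather than transgenes, since each slide holds 1 genotype. Of 276 genes called between the AD and WT slides of cortex, 162 had the same direction in the 3 other pairs of slides, a share of 0.587. Chance gives 1 in 8 if the pairs are independent, which those of hippocampus may not be where animals gave both regions. Of 55 genes with a log2 difference over 2, 50 had the same direction in the other pairs. These shares argue against slide differences as the whole cause. Called genes lay next to each other on chromosomes in 120 pairs, compared with a median of 55 and a highest value of 85 in 10000 random sets. The fullest windows of 50 tested genes held 19 called genes on chromosome 8 (Isyna1 to Zfp617), 18 on chromosome 17 (Zfp229 to Traf7) and 17 on chromosome 15 (Otulin to Slc25a32), with 2.92 as the mean. Stretches of chromosome carried with the transgenes or from another strain may therefore account for part of these calls, and an effect of the transgenes on other genes stays open.

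Falls outnumbered rises in Polb heterozygotes, 363 to 15, and most fallen genes were dim. With array brightness as a covariate 220 falls and 24 rises were called, so a linear effect of brightness is not the whole cause. Other effects on dim signal are not covered by that covariate. Among tested genes brighter than the median 38 fell and 13 rose, which argues against a shift confined to dim probes, although 325 of the falls lay below it. Normexp called 3 genes and quantile normalization 75, although these moved the median of all genes by only -0.02 and 0.03. All 363 genes stayed lower in both, with a median of -0.39 (median SE 0.14) with normexp and -0.53 (0.18) with quantile normalization instead of -0.78 (0.21), so the calls ended as the differences shrank more than their SE. A biological cause of the falls was not tested apart from the slides, which differ between the Polb labels, and with 1 mean per slide limma called 0 genes.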

How the results depend on the processing

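The fits without the defective array or doubted arrays, by the first or the wider rule, and with sex taken from the array, and the cortex lists without the defective array, were chosen only after the results were seen. Of 1415 gene results, 1296 kept their direction and side of the threshold with normexp, 1360 with quantile normalization, 1362 with the series table and 1324 without doubted arrays. Over all fits that left out 1 array, 27722 of 28440 did. These results include genes past the threshold in neither fit, which count as kept, so the shares say little about the calls. Of 241 pooled results 46 lost their call with 1 mean per slide, and of 147 pooled results 33 did in vehicle arrays alone. The values that reversed came with the mean of all probes: Stard4 in AD cortex (-0.31), Stard4 in AD carriers (-0.22) and Mbp between regions (0.10). Counts not named below stayed within 1.5 times under the setting given, and the cause of a change was not tested. Dim signal limits the falls: the median fallen gene in Polb heterozygotes was well above background on 81.2% of arrays.

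With normexp the cortex counts were 1705 (AD), 2529 (Polb), 1448 (ADPolb) and 37 (NR in WT), and 0 for a differing NR response; hippocampus counts were 0 (Polb), 85 (ADPolb) and 0 (ADPolb against AD), and pooled counts 390 (AD), 3 (Polb) and 3394 (region). Quantile normalization gave 0 for a differing NR response, 3 for Polb and 10 for ADPolb against AD in hippocampus and 75 for pooled Polb. The series table gave 1 for a differing NR response and 47 for pooled Polb. Without a filter on dim probes the counts were 1912 (Polb cortex), 95 (NR in WT cortex), 0 (differing response), 316 (Polb hippocampus), 338 (ADPolb against AD hippocampus), 1 (NR in Polb hippocampus) and 669 (pooled Polb). Without a sex term AD and ADPolb hippocampus had 629 and 618, and with age 0 genes had a differing response. The mean of all probes gave 128 for NR in WT cortex and 0 for a differing response. A fit of only the groups compared gave 299, 463 and 15 in cortex (AD, ADPolb, NR in WT) and 400, 419 and 736 in hippocampus (AD, Polb, ADPolb).

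Replicate numbers were not taken to pair the arrays: no comparison had a correlation over 0.1 in all 4 pairs (-0.550 to 0.518; up to 3 of 4 were over it). The number is also the array's place along the slide, so the block takes in position, and a cause was not tested. With a replicate block, cortex counts were 390 (AD), 579 (ADPolb), 119 (NR in WT) and 0 (differing response).

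Pooled AD counts were 2509 with no block, 216 with 1 mean per slide, 109 in vehicle arrays and 364 at a fold of at least 1.5. Those of Polb were 1535, 0, 231 and 233, and the region had 3161 with slide means and 2039 with the fold. The Polb level was -0.72 with slide means (adjusted p = 0.312) and -0.49 in vehicle arrays (0.214). Calls of gene lists numbered 175, with an estimated correlation 1 and with fry 50.

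Without the defective array the cortex counts were 1681, 2160 and 1665 against WT and 545 for NR in WT, and 67 cortex gene lists were called instead of 65. Without doubted arrays they were 320 (AD), 464 (Polb), 340 (NR in WT) and 1 (differing response), and in hippocampus 177, 1 and 62 against WT and 0 for ADPolb against AD, with 147 for pooled Polb and r = -0.616 instead of -0.519 for the hippocampus NR effect against the ADPolb effect over called genes; over all genes tested it was -0.327. By the wider rule the counts were 1360 (ADPolb cortex), 1 (ADPolb against AD cortex), 348 (NR in WT), 4 (NR over genotypes), 0 (differing response), 1, 55 and 0 (hippocampus Polb, ADPolb, ADPolb against AD), 1 (NR in AD hippocampus) and 80 (pooled Polb). With sex from the array they were 2 (differing response) and 196, 13 and 311 (hippocampus AD, Polb, ADPolb).

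With 1 array of the groups compared left out at a time, cortex counts ranged from 222 to 1246 (AD), 414 to 1555 (Polb), 320 to 1367 (ADPolb), 166 to 525 (NR in WT) and 0 to 6 (differing response). The defective array shares the cortex fit but is not among the arrays left out for the comparisons against WT and for NR in WT. ADPolb against AD and NR in Polb stayed at 0, NR in AD, in ADPolb and over genotypes at 0 to 1. Hippocampus counts ranged from 56 to 601 (AD), 0 to 9 (Polb), 75 to 165 (ADPolb), 2 to 92 (ADPolb against AD), 0 to 5 (NR in ADPolb, 5 and 4 without NR arrays 1 and 3) and 0 to 1 (NR over genotypes), and stayed at 0 for the others. In Polb hippocampus the counts were 1, 0, 0 and 0 without WT vehicle arrays 1 to 4 and 5, 0, 9 and 4 without Polb vehicle arrays 1 to 4. The pooled counts ranged from 769 to 1136 (AD), 268 to 640 (Polb; 640 without AD NR array 1 of hippocampus and 577 without that of cortex) and 5022 to 5873 (region), and the Polb level from -0.75 to -0.71. The correlation of the NR and ADPolb effects ranged from -0.676 to -0.388 in cortex and from -0.678 to -0.384 in hippocampus.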

Other observations

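In this part, the test of genes near Polb and the cortex lists without the defective array were chosen only after the results were seen.

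Between regions, several gene groups that the report leaves out differed. Circadian clock genes fell in hippocampus for 10 of 16 members (12, with 1 rise, adjusted over the list alone), with Dbp at -0.59 ± 0.12, Nr1d2 at -0.55 ± 0.11 and Clock at -0.34 ± 0.07; the adjusted p was 0.00237, and 0.24 with an estimated correlation. Cholesterol synthesis genes fell for 10 of 21 (11 adjusted over the list alone), among them Hmgcs1 (-0.38 ± 0.08), with 0.00121 and 0.25. Of 22 genes of tau, its kinases and phosphatases 8 fell, among them the Cdk5 activators Cdk5r2 (-0.95 ± 0.13) and Cdk5r1 (-0.47 ± 0.08), with 0.0223 and 0.26. Inhibitory neuron markers held 8 falls and 2 rises of 17, including Tac1 (-1.74 ± 0.32) and Vip (-1.24 ± 0.25), with 0.0278 and 0.28. Antigen presentation genes rose for 9 of 19 (12 adjusted over the list alone), Psmb8 at 0.70 ± 0.17, with 0.00565 and 0.52.

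Under NR, lists pointed different ways in the AD, Polb and ADPolb groups, where limma called 0 genes (between 193 and 1310 at an unadjusted p under 0.05). In cortex, meningeal markers were higher in 15 of 15 cases in Polb (median 0.62) and lower in 15 of 15 in ADPolb (-0.69), with adjusted p-values of 4.99e-06 and 3.34e-14 that became 0.47 and 0.18 with an estimated correlation. In AD cortex they were lower in 12 of 15 (-0.68; 0.00532, and 0.61 with an estimated correlation), and in 15 of 15 without the defective array (-0.52; 1.91e-08 and 0.37). Oligodendrocyte genes were higher with NR in ADPolb cortex (median 0.42), in AD hippocampus (0.54) and in ADPolb hippocampus (0.71) and lower in Polb hippocampus (-0.76), with adjusted p-values of 1.65e-06, 4.15e-12, 3.51e-08 and 5.64e-12 that became 0.79, 0.95, 0.90 and 0.30 with an estimated correlation. In AD and Polb cortex they did not pass (-0.26 and -0.12; 0.238 and 0.0825), but without the defective array they were lower in 22 and 18 of 23 (-0.24 and -0.13; 0.00149 and 0.0167, and 0.59 and 0.60 with an estimated correlation). Oxidative phosphorylation genes were higher in 56 of 57 cases in Polb hippocampus (median 0.18) and in 6 of 57 in ADPolb hippocampus (-0.15), with 6.00e-09 and 0.00104 that became 0.47 and 0.90 with an estimated correlation. These differences between genotypes were not tested as lists.

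Single arrays held large marker scores. Choroid plexus scores reached 4.07 on Polb NR 2 and 3.45 on AD vehicle 4 among cortex arrays, and blood scores reached 4.14 on Polb vehicle 2 of hippocampus. Among the hippocampus arrays of the ADPolb NR group, Thy1 stood at 9.10 on arrays 1 and 3 and at 7.72 and 7.12 on arrays 2 and 4. The value of 7.12 is at the level of the hippocampus WT groups (7.13 and 7.17) and goes against the AD label of that array. Arrays 2 and 4 also had the highest thalamus scores of all hippocampus arrays (1.13 and 0.59) and the highest striatum scores (0.88 and 0.65). Without array 4 every count that it enters stayed within 1.5 times. Xist stood at -1.90 on the male-labelled ADPolb vehicle array 1 of cortex. The 2 arrays labelled Polb vehicle with high Polb (1.42 in cortex, 1.25 in hippocampus) are each the only one of their group from an animal of 24 months, and the AD vehicle arrays with low Polb carry the same replicate number in both regions.

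Stretches of chromosome carried with the targeted Polb allele might add calls near Polb. Among the 50 tested genes nearest Polb on chromosome 8, 6 were called in heterozygotes, 3 higher (Smim19, Gins4 and 6820431F20Rik) and 3 lower (Defa2, Defa40 and Defb6). Windows of 50 genes elsewhere held up to 4 at the 95th percentile, 6 at the 99th and 13 at the highest, so the number is at the edge of what other windows hold and the test decides nothing.

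Other splits of the same arrays into groups of the same sizes tell whether chance can be excluded. Only the real split of 35 gave as many genes for AD, Polb and ADPolb against WT in cortex (854, 1083 and 886, highest others 114, 21 and 5). The same held in hippocampus (96, 23 and 141, highest others 0, 1 and 1) and for hippocampus against cortex (5236, highest other 2714). That argues against a random division of the arrays. The sides compared also lie on different slides, and in AD and ADPolb hippocampus they differ in labelled sex. Hence the splits cannot tell genotype or region from slide, sex or dissection. The 23 in Polb hippocampus became 0 to 9 on leaving out any 1 array. Chance is not excluded for NR in WT cortex, where 17 of 35 splits gave as many as 200 and the highest gave 604. Nor is it for ADPolb against AD in hippocampus, where 2 of 35 gave as many as 23 and the highest gave 224. Where limma called 0 genes every split gives as many, so the splits tell nothing about chance there. All 35 did for ADPolb against AD (highest other 1) and for NR in AD (1), Polb (0) and ADPolb (1) in cortex. The same holds for NR in WT (2), AD (4), Polb (5) and ADPolb (4516) in hippocampus. All 100 splits did for NR over genotypes in cortex (84) and hippocampus (1) and for a differing NR response in hippocampus (2209). The splits with 604, 224, 4516 and 2209 genes point to a structure of the samples other than their groups. For the pooled genotype contrasts 18 splits of slides are too few for a share under 0.05. The AD carrier split gave 949 with 308 as the highest other (1 of 18 as large), and the Polb split 378 with 834 (5 of 18). The 308 came from the division by Polb copy and the 834 from that by AD transgenes, so both follow the other genotype label. Divisions along neither label gave 634, 565 and 531 beside the 378 for Polb, which again points to a structure of the samples.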
